A study of Mus musculus with 4 samples.

How the data were processed

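Liver RNA of 4 mice treated with a scrambled control antisense oligonucleotide (ASO) and of 4 mice labelled Plin2-ASO was measured on 4 Agilent mouse oligonucleotide arrays of 2 colours. Per the labels, total RNA was amplified and labelled with the Ovation aminoallyl system, with Cy5 (red) for the control livers and Cy3 (green) for the livers labelled Plin2-ASO. Each array held 1 mouse of each group, and each array was 1 replicate. Arrays 1 to 4 set control mice 1, 2, 4 and 5 against mice 6, 7, 9 and 10. All arrays lay on 1 slide and were read in 1 scan, so no batch of arrays could be separated.

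Per the file headers, the spot intensities were extracted with Feature Extraction 9.5.1.1, and the mean signal and the median local background of each spot were used as deposited, before any background subtraction or dye normalization. The deposited log10 ratios of the same files are red over green after the software's background subtraction and dye normalization. The series table that the authors deposited holds log2 ratios of red over green: each column equalled the log10 ratio of its array converted to log2 for all 41174 probes, with a largest difference of 0 and a median of 0. Both kinds of ratio were used as alternatives only, with their sign turned. The direction rests on the dyes in the labels, and positive values mean higher in the livers labelled Plin2-ASO.

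Each array had 45018 spots, 1639 of them controls. Background was corrected with normexp (offset 50) and ratios were normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with the packages statmod 1.5.0 and data.table (version 1.17.8). Control spots were removed, spots marked as outliers by the scanning software in either channel were set to missing, and spots of a probe were averaged. A probe was kept when it was well above background on at least 3 of the 4 arrays in 1 channel, which left 27160 of 41174 probes. Each gene was represented by its brightest kept probe and had to be measured on at least 3 arrays. Of 18641 genes past the background filter 597 were left out for too few arrays, 18044 were tested and 16132 of these were measured on all 4 arrays. No spot was saturated.

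Probe names came from the reference table of assembly GRCm38.p6, used for names only. By the accession of the probe 22951 probes matched, by another RefSeq accession 124, by the symbol in the file 6582 and by an older symbol 3077, and 8440 kept the name in the file. Probe positions are those of the files, in mouse build mm7.

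The mean log2 ratio of each gene was tested against 0 with limma (lmFit with an intercept, eBayes, 7.21 total degrees of freedom, two-sided), and p was adjusted with Benjamini-Hochberg over all genes at 0.05. Every adjusted p of a gene in the text is from this fit, standard errors are its moderated ones and intervals are at 95%. A gene not well above background in 1 group on any array has only a bound on its fold. The 38 gene lists, fixed before the data were examined, cover lipid, sterol, glucose, amino acid, bile acid, xenobiotic and steroid metabolism, stress, immune and interferon responses, liver cell types, sex-biased genes, the clock, the cell cycle, ribosome, proteasome, lysosome and oxidative phosphorylation. The 37 lists with at least 5 members measured on all arrays were tested with camera at its preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry beside it. Camera and fry used only the list members measured on every array in the fit. Counts and medians use every member tested. Fry tests whether the genes of a list move on balance 1 way and does not compare them with other genes. Counts adjusted over the list alone use Benjamini-Hochberg within the list.

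The named genes were chosen by a rule fixed before the data were examined: the perilipins, the 10 highest and 10 lowest mean log2 ratios among changed genes with the same sign on all 4 arrays, the 4 members with the smallest p in each list past the threshold, and 3 members of each of 8 lists of lipid and glucose metabolism. Among the 10 highest and 10 lowest, names that are only accession, clone, RIKEN or Agilent identifiers were skipped. Members of other lists that moved against their list, genes marked as singled out, and the genes given under other observations were chosen after their values were seen. Of 34 named genes with other kept probes, 3 had a probe of opposite sign. Some genes that the rule chose are not reported here.

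The alternatives tried were no background correction, an offset of 16, median centring, the software's ratios, the series table, scaling between arrays, no filter or a strict filter on background, the mean of all kept probes, keeping outlier spots, separate channels with the intraspot correlation, the channels as independent samples, eBayes with trend and robust, array quality weights, an adjusted p under 0.1, all kept probes, and leaving out each array. A correction for probe GC content (a natural spline with 4 degrees of freedom per array), alone and without array 3, and cameraPR on all tested genes were added after the data were seen.

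The steps were tested on simulated data for this comparison with 18044 genes, 50 of them changed at each size. Of those, 0% were called at a log2 change of 0.5, 38% at 1, 86% at 2 and 98% at 4, and 0.893% of the calls were unchanged genes. Among 37 simulated lists the shifted one was called, with an adjusted p of 1.43e-30 by camera, and 0 others were. The simulated genes were independent of each other, while correlations within the real lists were estimated at up to 0.84. The simulation therefore does not show how often camera calls a list whose members move together.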

Results

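Perilipin 2 (Plin2) coats the lipid droplets in which liver cells store fat. Liver transcripts were compared between mice treated with an antisense oligonucleotide (ASO, a short modified nucleic acid that binds a transcript and lowers its level) against Plin2 and mice treated with a scrambled control ASO. The mice were male C57BL/6 animals on a high-fat diet and received 25 mg/kg into the abdomen, 2 injections a week, over 4 weeks. The 4 arrays carried 2 colours each: the liver of 1 control mouse was in the red dye (Cy5) and the liver of 1 mouse labelled Plin2-ASO in the green dye (Cy3). The arrays were numbered 1 to 4. No array had the dyes exchanged, so a dye effect of a single probe could not be separated from the treatment.

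The median spot signal was 330, 392, 244 and 499 in green and 375, 256, 637 and 260.0 in red on arrays 1 to 4, against median local backgrounds of 55.0 to 58.5 in green and 62.0 to 63.5 in red. Between 59.9% and 68.3% of the probes were well above background in green, and between 64.4% and 70.1% in red. No spot was saturated, and 18044 genes were tested. Array 3 stood apart from the others. Its log2 ratios correlated with those of the other arrays at a mean r of 0.33 across genes, against 0.51 to 0.65 for the other arrays; genes are not independent replicates. The scanning software marked 7.61% of its spots as outliers, against 1.5% to 3.83% on the other arrays. The correlation of the log2 ratio with probe GC content was -0.28 on array 3 and 0.26 on array 4, against 0.06 and 0.08 on arrays 1 and 2. The number of arrays limits the precision of every value.

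Plin2 itself, the target of the oligonucleotide, was not lower in the livers labelled Plin2-ASO. Its only probe (named Adfp in the files, transcript NM_007408, mouse build mm7, chromosome 4, 86060498 to 86060557) had log2 ratios of 0.24, 0.15, 0.83 and 0.36 on arrays 1 to 4. The mean was 0.40 ± 0.15 (SE, n = 4), 1.32-fold higher, with a 95% interval of 0.03 to 0.76 and an adjusted p of 0.155 by limma. Its level was high in both groups, at a log2 signal of 13.97 in the livers labelled Plin2-ASO and 13.57 in the control livers. A positive sign means a higher level in the livers labelled Plin2-ASO, and if the dyes or the labels were exchanged, every sign and direction given here would be mirrored. The site of the transcript that the oligonucleotide binds is not stated, so its place relative to the probe is unknown, and no exon annotation of mm7 was used here. Among the other perilipins, Plin3 fell by 0.75 ± 0.14 on the log2 scale (1.68-fold lower, adjusted p = 0.0192), lower on all 4 arrays; leaving out array 1 or 2 ended this call (adjusted p = 0.153 and 0.111). The mean log2 ratios of Plin1, Plin4 and Plin5 were 0.26 ± 0.39, 0.30 ± 0.38 and 0.19 ± 0.16 (SE, n = 4; adjusted p = 0.712, 0.659 and 0.50). Plin1 had a ratio of 1.96 on array 3 and of -0.57 to -0.10 on the others. Without array 3 its mean was -0.30, and without array 4 that of Plin4 was -0.15.

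The comparison asked which liver transcripts differ when Plin2 is targeted on a high-fat diet. In the livers labelled Plin2-ASO, a list of male-biased and growth hormone responsive liver genes was higher as a group by camera with its preset correlation. Of its members, Hsd3b5 was 34.1-fold higher (log2 ratio 5.09 ± 0.67, SE, n = 4). A list of female-biased liver genes was lower by the same test. Neither list passed camera with an estimated correlation (adjusted p = 0.508 for both). Of 24 cell cycle genes 18 fell, with a list median log2 ratio of -0.97 (adjusted p = 0.508 with an estimated correlation). Markers of stellate cells and fibrosis, of endothelial cells and of macrophages were lower by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.508, 0.660 and 0.660); Col1a1 was 7.72-fold and Gpnmb 6.52-fold lower, while 4 macrophage markers rose. Fatty acid, cholesterol and bile acid synthesis lists were higher and ribosomal protein genes lower by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.508, 0.660, 0.508 and 0.660), and no endothelial, cholesterol or ribosomal gene passed by limma without array 1 or without array 2. All these directions would be mirrored if the dyes or labels were exchanged.

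Of the 18044 genes, 1762 changed at an adjusted p under 0.05, of which 665 rose and 1097 fell. Of the 1658 changed genes measured on all 4 arrays, 1657 had the same sign on each. The median size of the change was 0.91 on the log2 scale, and 708 changed genes differed by more than 2-fold. The p-values measure the spread between the 4 pairs of mice, with the noise of their arrays included. A dye effect equal on all arrays would add no spread. Leaving out array 1 or 2 lowered the number of genes changed to 355 and 341, leaving out array 4 to 1092, and leaving out array 3 raised it to 5789. Of the 15 gene lists that passed camera with its preset correlation, 9 were higher and 6 lower, while 0 passed with an estimated correlation and 2 passed with fry. With an estimated correlation 2 lists had an unadjusted p under 0.05, and with fry 13. The 4 arrays leave the test with an estimated correlation few degrees of freedom, so failing it decides neither for nor against a list.

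**Figure D1:**
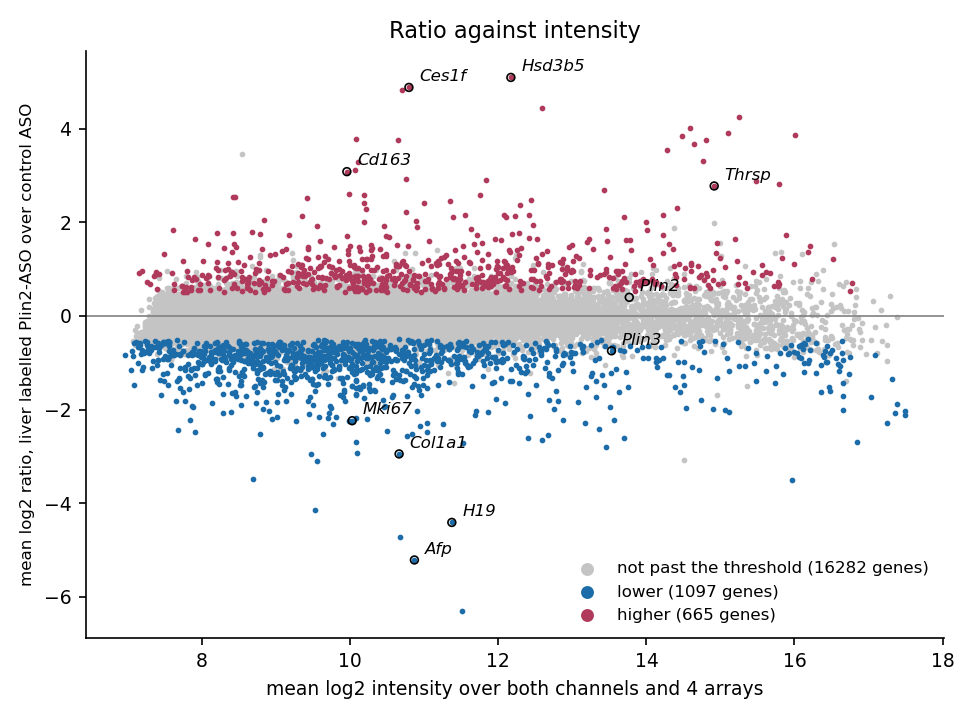
Mean log2 ratio (livers labelled Plin2-ASO over control livers) of each of the 18044 genes against its mean log2 intensity, with the changed genes in colour. The 665 genes that rose and the 1097 that fell spread over the range of intensities; the sign of every ratio would turn if the dyes or labels were exchanged.

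Among changed genes with a gene symbol and the same sign on all 4 arrays, Hsd3b5, a male-biased steroid dehydrogenase, had the highest mean log2 ratio (adjusted p = 0.00657). Next were the carboxylesterase Ces1f (4.88 ± 0.23, 29.4-fold, adjusted p = 0.000658) and Slco1a1, a transporter of organic anions (4.82 ± 0.41, 28.2-fold, adjusted p = 0.00172). The major urinary protein genes Mup5, Mup4 and Mup1 rose 19-fold, 16.1-fold and 14.6-fold. Cfd (adipsin, a protease that fat cells secrete) rose 13.7-fold, the fatty acid elongase Elovl3 13.5-fold, the sulfotransferase Sult2a8 12.7-fold and Cyp2f2 9.86-fold. Cfd read 1.1, 3.64, 6.45 and 3.91 on arrays 1 to 4, and the median of the 10 adipocyte markers measured was 1.08 on array 3 against -0.09 to 0.36 on the other arrays. Without array 2 the call of Cfd ended (adjusted p = 0.0881), and its mean log2 ratio was 4.67 without array 1 and 2.89 without array 3. Without array 4, which had the lowest ratio of each, the mean log2 ratios of Hsd3b5, Mup5, Mup4 and Mup1 were 6.08, 5.13, 4.81 and 4.60. Members of the Mup, Hsd3b, Ces1, Sult2a and Cyp families share sequence, so which member a probe of these families measured is uncertain.

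Among changed genes chosen in the same way, Afp had the lowest mean log2 ratio (-5.21 ± 0.52, SE, n = 4, 37.1-fold lower, adjusted p = 0.00283). It encodes alpha-fetoprotein, which the fetal liver makes in large amounts. The imprinted fetal RNA H19 was 21.3-fold lower (adjusted p = 0.00146) and the transporter Slc22a29 17.7-fold. Slc22a29 was well above background on 2 of the 4 arrays in the livers labelled Plin2-ASO. Apoc2, the cofactor of lipoprotein lipase, was 11.4-fold lower (-3.51 ± 0.19, SE, n = 4, adjusted p = 0.000979). Sprr1a was not well above background in any liver labelled Plin2-ASO and was at least 8.97-fold lower. The macrophage protease Mmp12 and the lectin Lgals3 were 7.74-fold and 6.98-fold lower.

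**Figure D2:**
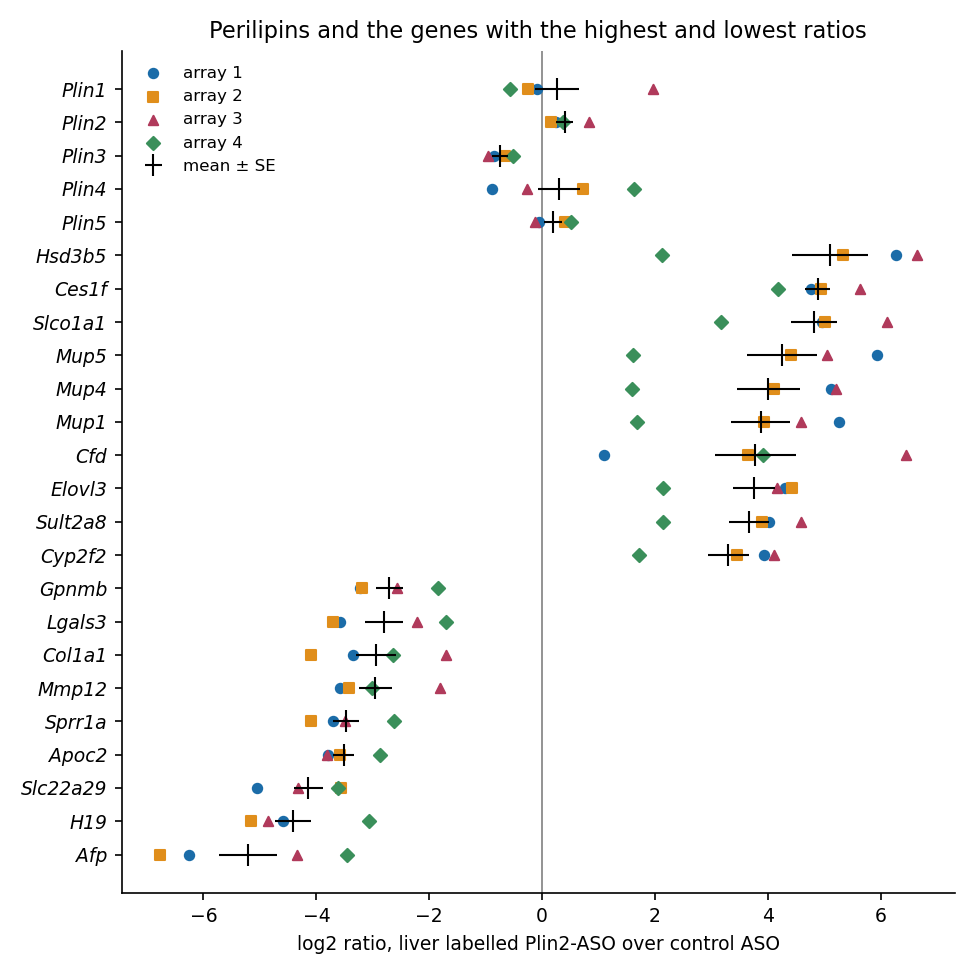
Log2 ratios (livers labelled Plin2-ASO over control livers) of the perilipins and of genes with the highest and lowest mean ratios under the naming rule. Each array is 1 point, shown with the mean ± SE. Plin2 lies between 0.15 and 0.83 on the 4 arrays, Hsd3b5 between 2.13 and 6.64 and Afp between -6.78 and -3.46; all signs would turn if the dyes or labels were exchanged.

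The male-biased list also holds growth hormone responsive genes. Of its 18 genes measured, 10 rose and none fell over all genes, and 16 rose adjusted over the list alone. Their median log2 ratio was 1.36 (camera adjusted p = 4.70e-12; adjusted p = 0.508 with an estimated correlation). Hsd3b5, Slco1a1, Elovl3 and Mup1 were the 4 with the smallest p. Array 4 had the lowest median, 0.60, against 1.66 to 2.24 on the other arrays. Of 15 female-biased genes, 7 fell and none rose, and 10 fell adjusted over the list alone (median log2 ratio -0.96, or -0.88 with the gene that has only a bound at its bound; camera adjusted p = 9.39e-05; adjusted p = 0.508 with an estimated correlation). The kinase receptor Ntrk2 was 5.72-fold lower (adjusted p = 0.00383) and Prom1 2.54-fold (adjusted p = 0.00545), each well above background on 1 of 4 arrays in the livers labelled Plin2-ASO. A second probe of Prom1 read -0.33, against -1.35 for the probe used. Hao2 was well above background on none of them and was at least 1.46-fold lower (adjusted p = 0.00545). The number of genes of the male-biased list that rose was 5 without array 1, 5 without array 2, 15 without array 3 and 12 without array 4. Without the same arrays in turn, 5, 6, 10 and 7 female-biased genes fell. The female-biased median was -1.92, -0.70, -1.52 and -0.63 on arrays 1 to 4. Cyp2b9 and Cyp2b13, singled out after their values were seen, did not pass by limma (adjusted p = 0.344 and 0.927). On arrays 1 to 4 Cyp2b9 read -2.51, 0.85, -2.04 and 0.18, and Cyp2b13 read -2.36, 2.22, -1.67 and 1.26.

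Of 24 cell cycle and DNA replication genes, 18 fell and none rose over all genes, and 20 fell adjusted over the list alone. The list had the smallest p of all (median log2 ratio -0.97 on all arrays together and -1.22 to -1.03 on single arrays; camera adjusted p = 2.22e-13; adjusted p = 0.508 with an estimated correlation; fry adjusted p = 0.0348). Cdc20, an activator of the anaphase-promoting complex, was 6.45-fold lower (-2.69 ± 0.17, SE, n = 4, adjusted p = 0.00125). The proliferation marker Mki67 was 4.72-fold lower, the replication helicase subunit Mcm6 4.08-fold and cyclin A2 (Ccna2) 3.98-fold. Without array 1 or 2, 12 and 11 members fell, without array 3, 21, and without array 4, 13.

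Markers of the cells between the hepatocytes were lower as groups. Of 21 stellate cell and fibrosis markers, 13 fell and none rose, and 17 fell adjusted over the list alone (median log2 ratio -1.04, or -1.01 with the gene that has only a bound at its bound; camera adjusted p = 2.01e-08; adjusted p = 0.508 with an estimated correlation). The collagens Col1a1 and Col3a1 fell by 2.95 ± 0.35 and 2.61 ± 0.30 on the log2 scale (SE, n = 4), the matrix protein Sparc by 1.73 ± 0.21 and the collagen cross-linking enzyme Loxl2 by 1.47 ± 0.19. Second probes of Col1a1, Col3a1 and Loxl2 read less, at -1.65, -1.17 and -0.60. Of 17 endothelial markers, 5 fell and none rose, and 7 fell adjusted over the list alone (median log2 ratio -0.59; camera adjusted p = 9.39e-05; adjusted p = 0.660 with an estimated correlation). Egfl7, Tie1, Vwf and the scavenger receptor Stab1 were 2.06-fold, 1.92-fold, 1.85-fold and 2.01-fold lower; a second probe of Vwf read -0.56, against -0.88 for the probe used. On array 3 the endothelial median was 0.10, against -0.96 to -0.74 on the other arrays. The number of stellate markers that fell was 6 without array 1, 5 without array 2, 17 without array 3 and 11 without array 4. Of the endothelial markers, none passed by limma without array 1 or without array 2 (5 and 6 had an unadjusted p under 0.05), 15 fell without array 3 and 4 without array 4. The highest adjusted p of Egfl7, Tie1, Vwf and Stab1 with array 1 or 2 left out was 0.0885, 0.111, 0.112 and 0.139.

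Macrophage markers moved both ways. Of 22 measured, 11 fell and 4 rose over all genes, and 15 fell and 4 rose adjusted over the list alone (median log2 ratio -0.91, mean -0.53; camera adjusted p = 1.03e-05; adjusted p = 0.660 with an estimated correlation). Gpnmb and Trem2, markers of lipid-laden macrophages, were 6.52-fold and 4.85-fold lower (adjusted p = 0.00211 and 0.00147), the lysosomal glycoprotein Cd68 3.43-fold and Itgax, the integrin Cd11c, 2.69-fold. The 4 that rose, singled out after their values were seen, were Cd163, Vsig4, Marco and Clec4f. They were 8.46-fold, 5.75-fold, 5.58-fold and 5.15-fold higher, Marco and Clec4f on 3 arrays each. Cd5l, like Clec4f a marker of resident liver macrophages, was 2.02-fold lower (adjusted p = 0.0470, and 0.227 and 0.216 without array 1 and without array 2), and the general macrophage marker Adgre1 read -0.80 (adjusted p = 0.107). Second probes of Gpnmb and Itgax read -1.49 and -0.26, less than the -2.71 and -1.43 of the probes used. Medians of the list were -1.26, -1.53, -0.29 and -0.38 on arrays 1 to 4. With array 1 left out 3 markers fell and 3 rose, with array 2 left out 4 fell and 2 rose, with array 3 left out 15 fell and 3 rose, and with array 4 left out 10 fell and 2 rose. The call of Itgax ended without array 1 (adjusted p = 0.0662) and without array 2 (adjusted p = 0.0636).

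Genes that make fat and sterols were higher as groups. Of 17 fatty acid synthesis genes, 5 rose and 1 fell over all genes, and 7 rose and 1 fell adjusted over the list alone (median log2 ratio 0.51; camera adjusted p = 3.36e-06; adjusted p = 0.508 with an estimated correlation). Thrsp, a lipogenic nuclear protein, rose 6.84-fold (2.77 ± 0.20, SE, n = 4, adjusted p = 0.00143), acetyl-CoA carboxylase 2 (Acacb) 4.31-fold, pyruvate kinase (Pklr) 2.86-fold and Acss2 3.06-fold; a second probe of Acacb read 1.5, against 2.11 for the probe used. The desaturase Scd2 fell by 1.16 on the log2 scale, and no member of the list fell without array 1 or without array 2. Fatty acid synthase (Fasn) and the desaturase Scd1, singled out after their values were seen, did not pass by limma. Their mean log2 ratios were 0.68 and 0.36 (adjusted p = 0.360 and 0.228), and on array 4 they read -0.75 and -0.20. Of 24 cholesterol synthesis and uptake genes, 5 rose and none fell, and 7 rose adjusted over the list alone (median log2 ratio 0.64; camera adjusted p = 3.36e-06; adjusted p = 0.660 with an estimated correlation). Mvk, Insig1, Tm7sf2 and Fdps were 1.65-fold, 2.65-fold, 2.82-fold and 3.73-fold higher; a second probe of Fdps read 0.26, against 1.90 for the probe used. The cholesterol median was -0.30 on array 4, against 0.64 to 1.26 on the other arrays. Without array 1 or without array 2, none of the cholesterol genes passed by limma (6 had an unadjusted p under 0.05 each time), with adjusted p up to 0.130, 0.0951, 0.0954 and 0.137 for Mvk, Insig1, Tm7sf2 and Fdps; 7 rose without array 3 and 13 without array 4. Of the fatty acid synthesis genes, 3 rose without array 1, 3 without array 2, 8 without array 3 and 5 without array 4, and Acss2 had an adjusted p of 0.0686 without array 1 and 0.0608 without array 2.

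Of 20 genes of bile acid synthesis and transport, 5 rose and 1 fell over all genes, and 11 rose and 1 fell adjusted over the list alone (median log2 ratio 0.48; camera adjusted p = 1.71e-05; adjusted p = 0.508 with an estimated correlation; fry adjusted p = 0.0414). Beside Slco1a1, the sterol hydroxylase Cyp8b1, which sets the share of cholic acid, rose 4.45-fold (2.15 ± 0.14, SE, n = 4, adjusted p = 0.00125). The sterol hydroxylase Cyp27a1 rose 2.70-fold and the bile acid uptake carrier Slc10a1 2.44-fold. The sterol exporter Abcg5 fell by 1.32 on the log2 scale. Without array 3, 8 members rose, and without array 1 or without array 2 none fell.

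**Figure D3:**
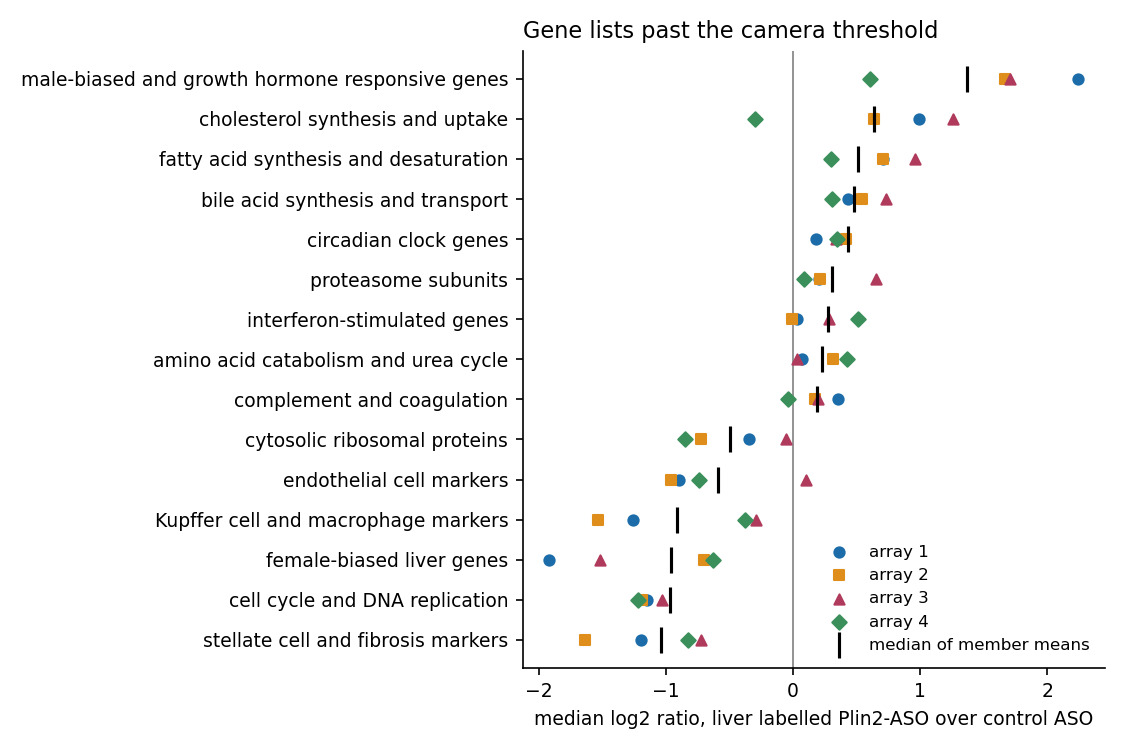
Median log2 ratio (livers labelled Plin2-ASO over control livers) of each of the 15 gene lists past the threshold, with 1 point per array and the median over the mean ratios. The cell cycle list lies between -1.22 and -1.03 on the 4 arrays and the male-biased list between 0.60 and 2.24, while cholesterol synthesis spans -0.30 to 1.26; all signs would turn if the dyes or labels were exchanged.

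The other lists of lipid and glucose metabolism did not pass. Of 19 lipid droplet proteins and lipases, 2 rose and 1 fell (camera adjusted p = 0.215), with 3 and 2 adjusted over the list alone. Fitm1, which partitions fat into droplets, and hormone-sensitive lipase (Lipe, on 3 arrays) were 2.10-fold and 1.67-fold higher (adjusted p = 0.0153 and 0.0412); other probes of Lipe read 0.07 and 0.86, against 0.74. None of 18 genes of mitochondrial fatty acid oxidation passed by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.832), and 3 had an unadjusted p under 0.05, all lower; Acadvl, Bdh1 and Etfb read -0.38, -0.46 and -0.41. Of 23 PPAR-alpha target genes, 1 rose and 1 fell (camera adjusted p = 0.629), with none and 1 adjusted over the list alone: the fatty acid binding protein Fabp1 was 4.02-fold lower (on 3 arrays, adjusted p = 0.00657) and Acsl1 1.78-fold higher (adjusted p = 0.0498), while Ehhadh read -0.87 (adjusted p = 0.0590). Of 21 genes of triglyceride synthesis and lipoprotein assembly, 1 rose and 5 fell, with 2 and 6 adjusted over the list alone (camera adjusted p = 0.551), among them Apoa4 (4.15-fold lower), Apoc3 (1.79-fold lower) and Agpat2 (1.82-fold higher, on 3 arrays). Of 15 genes of fatty acid uptake, 2 rose and 4 fell, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.673); lipoprotein lipase (Lpl) was 5.31-fold lower and the fatty acid carrier Cd36 4.66-fold. Of 20 genes of gluconeogenesis, glycogen and insulin signalling, 2 rose and 2 fell, with 6 and 3 adjusted over the list alone (camera adjusted p = 0.0525). The glycogen-targeting subunit Ppp1r3b and glucose-6-phosphatase (G6pc) were 2.05-fold and 1.93-fold higher, and Igfbp1 1.73-fold lower. A second probe of Apoc3 read -0.50, against -0.84 for the probe used. These counts moved when 1 array was left out, and 16 or 21 of the triglyceride and lipoprotein genes were then measured. Of those genes, none passed by limma without array 1 (7 had an unadjusted p under 0.05), 1 fell without array 2, 4 rose and 6 fell without array 3, and 3 fell without array 4. Of the fatty acid uptake genes, 2 fell without array 1, 1 fell without array 2, 3 rose and 6 fell without array 3, and 2 rose and 2 fell without array 4. Of the glucose metabolism genes, 1 rose without array 1, none passed by limma without array 2 (6 had an unadjusted p under 0.05), 7 rose and 3 fell without array 3, and 2 rose without array 4. No lipid droplet gene or PPAR-alpha target passed by limma without array 1 (4 and 4 had an unadjusted p under 0.05) or array 2 (3 and 5). Without array 3, 4 droplet genes rose and 2 fell, 1 PPAR-alpha target rose and 3 fell, and 3 genes of mitochondrial fatty acid oxidation fell. Without array 4, 1 droplet gene rose and 1 fell, and 1 PPAR-alpha target rose and 3 fell.

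Several of these calls ended with 3 arrays in the fit, while the ratios stayed about as large. With array 1 or 2 left out, the log2 ratios of Fitm1, Acsl1, Apoc3, G6pc and Igfbp1 were 0.96 to 1.11, 0.79 to 0.86, -0.90 to -0.84, 0.92 to 0.94 and -0.77, and the highest adjusted p was 0.101 for Fitm1, 0.227 for Acsl1, 0.0822 for Apoc3, 0.0752 for G6pc and 0.142 for Igfbp1, and Igfbp1 had 0.0624 without array 4. Apoa4 did not pass without array 1 (adjusted p = 0.0603), and neither Cd36 nor Ppp1r3b without array 2 (adjusted p = 0.0515 and 0.0659). Without array 3, Acadvl, Bdh1 and Ehhadh passed (adjusted p = 0.0480, 0.0478 and 0.0378), and Ehhadh also without array 4 (adjusted p = 0.0156).

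Ribosomal protein genes were lower as a group. Of 39 measured, 7 fell and none rose over all genes, and 20 fell adjusted over the list alone (median log2 ratio -0.50; camera adjusted p = 3.83e-08; adjusted p = 0.660 with an estimated correlation). Rplp2, Rps2, Rplp0 and Rplp1 were 1.83-fold, 1.78-fold, 1.64-fold and 2.08-fold lower, but 2 other probes of Rplp0 read 0.27 and 0.09, and a second probe of Rps2 read -0.31, against -0.83 for the probe used. The ribosomal median was -0.05 on array 3 and -0.85 to -0.35 on the other arrays. None of the 39 passed by limma without array 1 or without array 2 (17 and 11 had an unadjusted p under 0.05), 32 fell without array 3 and 2 without array 4. With array 1 or 2 left out the adjusted p of Rplp2, Rps2, Rplp0 and Rplp1 reached 0.0740, 0.0900, 0.131 and 0.116, and without array 4 it was 0.0575 for Rplp0 and 0.0512 for Rplp1. Of 28 proteasome subunit genes, 2 rose and none fell, and 2 rose adjusted over the list alone (median log2 ratio 0.31; camera adjusted p = 0.00200; adjusted p = 0.660 with an estimated correlation). Psmd7 (on 3 arrays) and Psmd1 were 2.00-fold and 1.56-fold higher, while Psmc3 and Psmc2 read 0.63 and 0.42 (adjusted p = 0.0781 and 0.0947). A further probe of Psmd7 read -0.04 and one of Psmc2 -0.27. The proteasome median was 0.66 on array 3 and 0.09 to 0.21 on the other arrays, and 0.15 with array 3 left out. No proteasome gene passed by limma without array 1, without array 2 or without array 4 (2, 2 and 6 had an unadjusted p under 0.05), and 6 rose and 1 fell without array 3, where Psmc3 had an adjusted p of 0.00631; that of Psmd1 was 0.148, 0.183 and 0.0726 without arrays 1, 2 and 4.

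Of 20 circadian clock genes, 3 rose and none fell over all genes, and 8 rose and 1 fell adjusted over the list alone (median log2 ratio 0.44; camera adjusted p = 0.00205; adjusted p = 0.508 with an estimated correlation). The repressor Nfil3 and the activator Npas2 were 1.75-fold and 1.47-fold higher, and Cry1 read 0.61 (adjusted p = 0.0512). Other members of the clock list read lower. Nr1d1, Dbp and Per1, singled out after their values were seen, read -0.65, -0.29 and -0.30 (adjusted p = 0.0586, 0.362 and 0.463 by limma). Of 28 interferon-stimulated genes, 3 rose and none fell, and 3 rose adjusted over the list alone (median log2 ratio 0.28; camera adjusted p = 0.00347; adjusted p = 0.668 with an estimated correlation). Irf7, the inducer of interferon genes, Ifit3 and Ifi27 were 2.03-fold, 1.57-fold and 1.51-fold higher, and Stat2 read 0.54 (adjusted p = 0.0831). A second probe of Ifi27 read 0.24, against 0.59 for the probe used. The interferon list did not pass without array 4 (median log2 ratio 0.08, camera adjusted p = 0.115), with array quality weights (0.12, adjusted p = 0.137) or with the GC correction without array 3 (0.23, adjusted p = 0.0511). None of the clock or interferon genes passed by limma without array 1 or without array 2, with adjusted p up to 0.113 for Nfil3, 0.256 for Npas2, 0.118 for Irf7, 0.186 for Ifit3 and 0.228 for Ifi27. Without array 4, 1 gene of each list rose, and Npas2, Ifit3 and Ifi27 had adjusted p of 0.162, 0.156 and 0.0839. Without array 3, 9 clock genes rose and 2 fell and 4 interferon genes rose and 3 fell, with Cry1 and Stat2 at adjusted p of 0.00509 and 0.0164.

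Of 28 genes of amino acid catabolism and the urea cycle, 6 rose and 1 fell over all genes, and 9 rose and 2 fell adjusted over the list alone (median log2 ratio 0.23; camera adjusted p = 0.00347; adjusted p = 0.508 with an estimated correlation). Ornithine aminotransferase (Oat) and proline dehydrogenase (Prodh) were 2.89-fold and 2.33-fold higher, Shmt1 and histidine ammonia-lyase (Hal) 1.66-fold and 1.58-fold, and Psat1, an enzyme of serine synthesis, fell by 0.76 on the log2 scale, though no member fell without array 1 or without array 2. With the log ratios centred on the median of each array in place of loess, the list did not pass (camera adjusted p = 0.130). The median of the amino acid list was 0.42 on array 4 and 0.03 to 0.31 on the other arrays, and 0.12 with array 4 left out. Of 24 complement and coagulation genes, 5 rose and 2 fell, and 6 rose and 4 fell adjusted over the list alone (median log2 ratio 0.19; camera adjusted p = 0.0373; adjusted p = 0.668 with an estimated correlation). C6 was 6.43-fold higher, Mbl1 2.03-fold, F11 1.85-fold and F7 1.59-fold, while C3 and prothrombin (F2, on 3 arrays) fell by 1.04 and 0.80 on the log2 scale. This list did not pass without array 1 (median log2 ratio 0.09, camera adjusted p = 0.147) or without array 3 (median log2 ratio 0.16, camera adjusted p = 0.0854). With array 1 or 2 left out the adjusted p reached 0.143 for Shmt1, 0.174 for Hal, 0.0948 for Mbl1, 0.121 for F11 and 0.173 for F7. C6 had an adjusted p of 0.0571 without array 2, and Shmt1 and F7 of 0.0854 and 0.0663 without array 4. The numbers of amino acid genes that rose were 2, 2, 10 and 3 without arrays 1, 2, 3 and 4, and those of complement and coagulation genes 1, 0, 7 and 4; those of complement and coagulation genes that fell were 0, 0, 4 and 1.

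The remaining lists did not pass camera, several of them with members that moved both ways. Of 25 genes of xenobiotic metabolism, 6 rose and 2 fell, with 7 and 6 adjusted over the list alone (camera adjusted p = 0.186). Of 22 genes of steroid and retinoid metabolism, 7 rose and 6 fell, with 9 and 6 adjusted over the list alone (camera adjusted p = 0.462). Of 22 hepatocyte identity genes, 2 rose and 3 fell, with 4 and 6 adjusted over the list alone (camera adjusted p = 0.551). Of 21 acute phase genes, 2 rose and 2 fell, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.390). Of 20 NRF2 and glutathione genes, 2 rose and 1 fell in both counts (camera adjusted p = 0.688). None of 23 genes of the unfolded protein and integrated stress response passed by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.845), and 4 had an unadjusted p under 0.05 in each direction. Of 18 chemokines and cytokines 3 fell, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0961). Of 22 lysosome and autophagy genes 1 rose and 2 fell, with 1 and 6 adjusted over the list alone (camera adjusted p = 0.274). Of 35 genes of oxidative phosphorylation 2 fell, with none adjusted over the list alone (camera adjusted p = 0.258). Without array 3, 11 of 33 oxidative phosphorylation genes fell and 1 rose, and without array 1, 2 or 4 none passed by limma (4, 3 and 3 had an unadjusted p under 0.05). For steroid metabolism 3 rose and 2 fell without array 1, 2 and 2 without array 2, 9 and 6 without array 3 and 6 and 6 without array 4; for xenobiotic metabolism 3 rose and 0 fell, 4 and 0, 8 and 3, and 4 and 2. For hepatocyte identity these counts were 0 and 2, 0 and 1, 5 and 5, and 2 and 1, for the acute phase 3 and 0, 0 and 1, 3 and 3, and 1 and 4, and for NRF2 and glutathione 0 and 1, 0 and 1, 3 and 3, and 1 and 2. For chemokines and cytokines they were 1 and 0, 0 and 0, 0 and 5, and 0 and 3, and for lysosome and autophagy 0 and 0, 0 and 0, 1 and 6, and 0 and 3; where none passed by limma, 5 chemokine genes without array 2, and 3 and 6 lysosome genes without arrays 1 and 2, had an unadjusted p under 0.05. Of the unfolded protein list, 1 gene fell without array 3 and 1 rose without array 4, while none passed without array 1 or 2 (3 and 3 had an unadjusted p under 0.05). The medians of 2 lists, unfolded protein (-0.19) and hepatocyte identity (-0.12), lay below 0 while camera placed the list higher than the other genes. Camera used only their 20 and 19 members measured on all arrays. With all tested genes, cameraPR placed both lists lower (adjusted p = 0.761 and 0.832). The cholangiocyte list had a median of 0.04, a mean of -0.30 and a lower position by camera, and the triglyceride list a median of 0.00, a mean of -0.19 and a lower position.

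Markers of other cell types were counted in the same way. Of 11 B and plasma cell markers 2 fell, or 3 adjusted over the list alone (camera adjusted p = 0.0525). Of 11 T and NK cell markers 1 rose, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.312). Of 11 neutrophil markers 2 fell, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.659). Of 8 genes of antigen presentation by MHC class II 1 fell and of 10 cholangiocyte markers 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.285 and 0.673). Of 8 erythroid markers 2 rose and 1 fell in both counts (camera adjusted p = 0.0975), and of 10 adipocyte markers 3 rose and 1 fell, with 3 and 2 adjusted over the list alone (camera adjusted p = 0.462). Without array 1, none of the B cell, T and NK cell, MHC class II or erythroid markers passed by limma (2, 1, 1 and 3 had an unadjusted p under 0.05), 1 neutrophil and 1 cholangiocyte marker fell, and 2 adipocyte markers rose and 1 fell. Without array 2, 1 erythroid marker rose, 1 neutrophil marker fell, 1 adipocyte marker rose and 1 fell, and none of the B cell, T and NK cell, MHC class II or cholangiocyte markers passed (2, 1, 1 and 2 had an unadjusted p under 0.05). Without array 3, 4 B cell markers fell, 2 T and NK cell markers rose and 3 fell, 3 neutrophil markers rose and 4 fell, 2 cholangiocyte markers rose and 2 fell, 2 erythroid markers rose and 1 fell, 1 MHC class II gene fell, and 4 adipocyte markers rose and 3 fell. Without array 4, 2 B cell markers, 1 T and NK cell marker, 1 neutrophil marker, 2 cholangiocyte markers and 2 MHC class II genes fell, 2 erythroid markers rose, and 2 adipocyte markers rose and 1 fell. Exocrine pancreas markers were measured for 4 genes, none of which passed (1 rose without array 3), and were too few to test as a list.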

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

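The tests of exchanged dyes, of second probes of the called genes and of macrophage markers were chosen after the results were seen; the tests of probe pairs, of fat genes, of GC content (with a correction added after the data were examined) and of sign patterns were set down before their own results were seen. Of 135 sets of 4 values, 5 had 1 array far from the other 3, and chance alone marks about 1 in 20. Elovl3 had a log2 ratio of 2.14 on array 4 and of 4.15 to 4.43 on the others. Thrsp had 2.04 on array 4 and 2.93 to 3.07 on the others. Ccna2 had -1.44 on array 3 and -2.21 to -2.16 on the others. The median of the B and plasma cell markers was -0.41 on array 2 and -0.16 to -0.14 on the others. The standard deviation of the log2 ratio was 0.68 on array 3 and 0.56 to 0.58 on the others.

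Plin2 read higher, not lower, in the livers labelled Plin2-ASO, against the purpose of the oligonucleotide. A dye effect that follows probe GC content is argued against as the whole cause, since the ratio was 0.41 ± 0.15 (SE, n = 4) after correction for GC. A dye effect of this single probe stays open, and the comparison of probe pairs cannot decide it. Of 10180 pairs of probes for the same gene with no 15-base stretch in common, 26.0% differed by the Plin2 ratio or more. Such differences hold the noise of both probes at any intensity and every cause of disagreement. A dye effect that hid a lowered transcript would also have to exceed the Plin2 ratio. Exchanged dyes or labels also stay open and cannot be told apart from the labels by these arrays, since no dye was swapped; with every sign turned, Plin2 would stand at 75.9% of the control level. The biological alternatives, such as an oligonucleotide that does not lower this part of the transcript, were not tested.

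Cell cycle, stellate and macrophage lists read lower and the male-biased list higher in the livers labelled Plin2-ASO. Dye effects of single probes would give second probes of either sign, but of the 22 changed members with a second probe (of 56), 100% had second probes of the same sign. Among all probe pairs, most of them of genes not chosen for a change, 66.3% shared a sign. The second probes argue against dye effects of single probes as the whole cause for these 22 members only. A dye effect shared by all probes of a gene would keep the sign and cannot be told apart. A trend with GC content is argued against too, since 4 of the 4 lists passed in the same direction after the correction. Fewer macrophages of every kind, and nothing else, would lower all their markers, but 4 of 22 were higher past the threshold while 11 were lower. These counts were known before the test was chosen, and a loss of only some kinds of macrophage was not tested. An exchange of dyes or labels would mirror all 4 lists and stays open, as does the treatment itself, which the dyes follow on every array.

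The ratios of array 3 correlated least with those of the others. Correction for GC content raised its mean correlation from 0.33 to 0.38, against a lowest value of 0.68 among arrays 1, 2 and 4, so GC content is not the whole cause. The adipocyte list reads highest on array 3, with Cfd at 6.45 and Adipoq at 4.10, and adipose tissue in the liver labelled Plin2-ASO of array 3 may be the source, but the test does not settle it. Of 12 fat genes in no other list, chosen before their values were seen, 8 had their highest ratio on array 3, against 45.0% of all genes (exact binomial p = 0.112, one-sided). Their median was 0.63 there and -0.10 to 0.15 on the others. The binomial test takes the 12 genes as independent, but array 3 holds 1 pair of mice, so its p does not measure the spread between mice. Aqp7, Slc36a2 and Ebf2 were well above background on only 2 arrays in 1 of the groups. Ucp1 and Cox8b, singled out after their values were seen, were not among the 12. On array 3 they read 5.04 and 4.2, against -0.39 to -0.33 and 0.05 to 0.47 on the others. These ratios lie in the direction that adipose tissue would give. Ebf2, Kcnk3 and Prdm16, which were among the 12, had their lowest ratios on array 3 (-0.49, -0.19 and -0.17). Differences between the mice themselves were not tested.

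The 4 arrays allow 8 patterns of turned signs, too few for a share under 0.05. For genes changed, 1 of the 8 patterns, the real one, gave as many as 1762, and the highest other gave 1. For gene lists, 3 of the 8 gave as many as 15, the highest other gave 19 and the lowest 7. Camera at its preset correlation thus called lists in every turned pattern, although at most 1 gene passed there.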

How the results depend on the processing

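The correction for probe GC content, alone and without array 3, and cameraPR were chosen after the results were seen; the other alternatives were planned. The number of genes changed was 1762 and stayed within 1.5 times of that, at 1275 to 2582, except with trend and robust eBayes (932), an adjusted p under 0.1 (2998), array quality weights (7025) and the GC correction without array 3 (5667, of which 1725 were among the 1762). With 1 array left out it ranged from 341 to 5789. The array weights were 2.84, 1.96, 0.22 and 0.80, so array 3 counted least; the looser threshold admits more genes by construction, and for the other settings the cause was not tested. The share of changed genes that were higher lay between 34.6% and 43.5%.

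Plin2 stayed positive and short of the threshold throughout, between 0.25 and 0.48 with 1 array left out; it has 1 probe, so no other probe could be tried. Of the gene lists called, 0 of the 15 passed with an estimated correlation and 2 with fry. The test with an estimated correlation takes its degrees of freedom from the 4 arrays, so few lists could pass it. The bile acid list, with an estimated correlation of only 0.05, went from an unadjusted camera p of 3.70e-06 to 0.0324. The cause of the fry result was not tested. Under the other settings 14 to 18 lists passed, and 12 of the 15 kept their direction and side of the threshold in all of them. The exceptions were complement and coagulation, interferon-stimulated genes and amino acid catabolism. Complement and coagulation had adjusted p from 0.0501 to 0.358 in the 6 settings where it failed, with median centring highest. The interferon list failed with array quality weights, without array 4 and with the GC correction without array 3 (adjusted p = 0.137, 0.115 and 0.0511), and amino acid catabolism with median centring (adjusted p = 0.130). Of 92 other named genes, 40 kept direction and side of the threshold in every setting. Of their 1817 values, 146 no longer passed, 32 newly passed and 4 reversed. Plin1 reversed with array weights (-0.13), without array 3 (-0.30, with a range of -0.30 to 0.54 over the arrays left out) and with the GC correction without array 3 (-0.38). Plin4 reversed without array 4 (-0.15, range -0.15 to 0.69); neither passed in any of these, and the ratios of these arrays, 1.96 for Plin1 and 1.63 for Plin4, were the highest. A block for slide or scan was not run, since there was 1 slide and 1 scan. Between 59.9% and 70.1% of probes per channel were well above background, and a fold is a bound only where no array of 1 group was; those of Ntrk2, Prom1, Slc22a29 and Gpc3, above it on 1 or 2 of 4 arrays labelled Plin2-ASO, are as measured and may be limited by background.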

Other observations

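The genes in this part were chosen after their values were seen, no test was planned for them, and their directions would be mirrored if the dyes or labels were exchanged. Abundant products of hepatocytes moved both ways. Albumin (Alb) fell by 1.70 ± 0.15 and apolipoprotein E (Apoe) by 1.88 ± 0.13 on the log2 scale (SE, n = 4, adjusted p = 0.00172 and 0.00125), and Ahsg, measured on 3 arrays, was 6.51-fold lower, while Mup1 rose 14.6-fold. Of 22 hepatocyte identity genes 2 rose and 3 fell (camera adjusted p = 0.551), and without arrays 1 to 4 in turn 0, 0, 5 and 2 rose and 2, 1, 5 and 1 fell. Genes known from the fetal liver did not all move with Afp and H19: Dlk1 read 0.21 (adjusted p = 0.535), the glypican Gpc3, well above background in 2 of the 4 livers labelled Plin2-ASO, was 3.27-fold lower, and Igf2, not well above background in any liver labelled Plin2-ASO, was at least 1.88-fold lower. The call of Igf2 ended without array 1 or 2 (adjusted p = 0.0580 and 0.0857) and that of Gpc3 without array 2 (adjusted p = 0.0509). Gfra1, a receptor of neurotrophic factors, and Mia2, a secretory pathway protein, were 8.68-fold and 4.36-fold higher (adjusted p = 0.000658 and 0.00125).

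Several genes split the arrays in pairs and did not pass. Cyp4a14, a fatty acid hydroxylase and PPAR-alpha target, had log2 ratios of -5.87, -0.50, -5.48 and -0.48 on arrays 1 to 4 (adjusted p = 0.0952). Moxd1 had 6.39, 0.16, 6.15 and 1.13 (adjusted p = 0.0884); it was well above background in 1 of the 4 control livers, so the size of its ratios is set in part by the background. On array 3 alone, the brown fat gene Ucp1 read 5.04, against -0.39 to -0.33 on the others, Cox8b 4.2 against 0.05 to 0.47, and the adipocyte hormone Adipoq 4.10 against 0.00 to 0.52.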
